A study of Mus musculus with 9 samples.

How the data were processed

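RNA of BeCon cells, the mouse ovarian tumor cells of this series, was measured by poly(A)-selected, strand-marking RNA sequencing in 9 libraries. In 8 of them the cells came from the ascites of tumor-bearing B6 mice given vehicle (4 libraries) or YKL-05-099 (4 libraries), an inhibitor of the salt-inducible kinases, and had been sorted as viable CD45-negative, MHC class I-positive cells, per the labels. The remaining library came from BeCon cells grown in culture and has no replicate. Groups and replicate numbers were taken from the sample titles. The titles name mice treated as groups and number the libraries, but do not say whether a library is 1 mouse or a pool, so p-values measure the spread between these libraries. The library names of the vehicle mice share a prefix and those of the treated mice share another, so a cage or batch behind that prefix, if there was any, cannot be told apart from treatment.

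The deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene and library, as the authors computed them, with a status beside each value, per the file headers. The submitters' processing notes name bcl2fastq 2.19 and the GRCm38 genome build. The aligner, the quantification program and its settings are not given in the sources used here. The table held 48302 rows. From rows with the same gene identifier the one with the longest locus was kept, which left out 65 rows, and 7 genes with a failed estimate in any library were left out because the value beside it was 0. This left 48230 genes, whose FPKM summed to between 453169 and 482851 per library. Between 11421 and 11893 genes per library reached an FPKM of 1. Mitochondrially encoded genes were not analysed here. Coordinates are those of the deposited table on GRCm38, counted from 1.

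FPKM values are not counts, and whole reads could not be recovered. The lowest values of 5751 genes with a single transcript of at least 2 kb, multiplied by transcript length, piled up at what 1 fragment is worth. The pile lay at a depth of roughly 24000000 to 37000000 fragments per library, an approximate value that gives no interval for a single gene. The vehicle libraries stood at about 26000000, 37000000, 30000000 and 34000000 fragments, and the cultured library at 29000000. A value of exactly 0 is given as listed at 0.

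The treatment comparison used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the mean-variance trend, no pairing and no rescaling of the deposited values, on genes with an FPKM of at least 1 in at least 4 of the 8 mouse libraries. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Gene lists, 56 in all, were written from textbook knowledge, and 50 had at least 5 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Each call is set beside the adjusted p from an estimated correlation. The cultured library was compared by a rule of size with no test. A gene counted as apart when its value lay outside the range of all 8 mouse libraries and at least 2 log2 units from the vehicle mean. Genes entered with an FPKM of at least 1 in 4 mouse libraries or in the cultured one. The median difference of each list was placed among 10000 random lists of the same size matched on mean expression over 20 bins.

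The gene lists, the rule for the genes named and the alternatives given below were fixed before the data were examined. The rule took in each direction the 12 genes with the largest change among those called with a mean FPKM of at least 1, leaving out predicted or unnamed genes. It also took up to 4 members with the smallest p from each list described, and Sik1, Sik2 and Sik3. For the cultured cells it took the 10 largest differences in each direction with an FPKM of at least 5 in the higher group, and up to 3 members per list described. Some genes that the rule took are not reported here. Near-identical gene copies (the alpha and beta globin genes, Apol9a and Apol9b, the H2 and Gbp families, immunoglobulin segments) can share reads, and their separate values are uncertain.

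The functions were tested on simulated data. For the treatment comparison, run on 11788 genes, 99% of 100 genes changed by 1 log2 unit and 41% of 100 genes changed by 0.3 were recovered, and 6 of 11588 unchanged genes were called. For the rule of size, run on as many genes, 99.5% of 200 genes moved by 3 log2 units were recovered and 5 unchanged genes were called apart. Changes were planted in 200 genes only, all above a minimum level, with noise drawn independently for each gene. These rates therefore do not carry over to genes with low values, to correlated genes or to data where many genes change. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean FPKM of at least 5, median-of-ratios, quantile and TPM scaling, all 9 libraries in the fit, a replicate block, array weights, robust variance, a minimum change of 1, an adjusted p under 0.1, a leukocyte covariate, leaving out each library, and for lists an estimated correlation and fry. For the cultured cells they were a limma fit of all 9 libraries and a difference of at least 1. Fits on genes at an FPKM of at least 1 in culture and on protein-coding genes were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.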

Results

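Gene expression was measured in BeCon mouse ovarian tumor cells sorted from the ascites of tumor-bearing mice, in 4 libraries after vehicle and 4 after YKL-05-099 treatment, and in 1 library of the same cells in culture. YKL-05-099 is a small-molecule inhibitor of the salt-inducible kinases, which restrain the CRTC coactivators of the transcription factor CREB and class IIa histone deacetylases. Sorting kept viable cells without the leukocyte antigen CD45 and with MHC class I. All values are FPKM from the deposited table, given as mean ± SD of 4 libraries for each mouse group. No pair of libraries held identical values. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, ran from 0.985 to 0.993 between vehicle libraries, from 0.989 to 0.992 between YKL-05-099 libraries and from 0.961 to 0.979 between both groups. The cultured library correlated with the mouse libraries at 0.856 to 0.873.

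**Figure D1:**
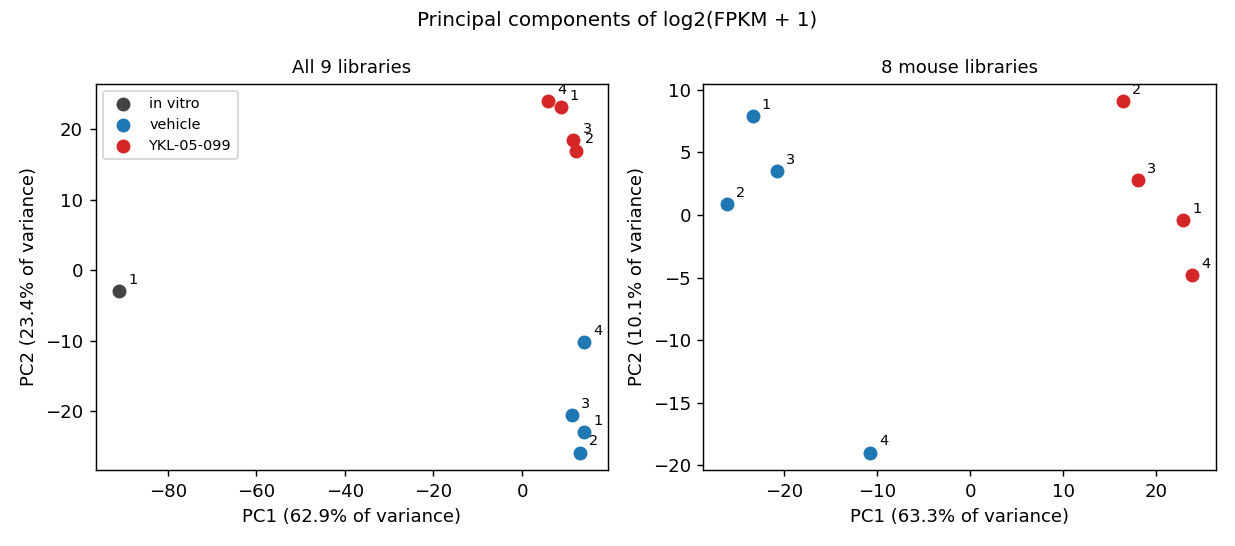
Principal components of log2(FPKM + 1) for all 9 libraries (left) and for the 8 mouse libraries (right), each point a library labelled with its replicate number. Among the mouse libraries the first component held 63.3% of the variance and parted the treatments, with vehicle 4 at -10.8 and the other vehicle libraries between -26.2 and -20.8.

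The first comparison asked what YKL-05-099 treatment of the mouse changed in the tumor cells. The genes with the largest rise were Has1, a hyaluronan synthase, at 2.43 ± 1.25 FPKM in vehicle and 19.3 ± 3.25 FPKM in YKL-05-099 cells, and the nuclear receptor gene Nr4a2, at 1.97 ± 0.245 and 14.8 ± 0.803 FPKM. The antiviral gene Oas2 rose from 1.19 ± 0.291 to 9.72 ± 1.44 FPKM. Apol9a, Hs3st1, Pde4d, Sfrp4, Gpr146, Shc2, Apol9b, Il33 and Ifi44 completed the 12 largest rises, with log2 fold changes from 1.80 to 2.63 among all 12. Among the 12 largest falls were 4 hemoglobin genes (Hbb-bs, Hbb-bt, Hba-a1, Hba-a2), the immunoglobulin genes Igkc and Igha, the macrophage-expressed genes Apoe, Lyz2 and C1qa, the acute-phase gene Saa3 and the monocyte chemoattractant gene Ccl2. The log2 fold changes of these genes ran from -4.92 to -2.65. The separate values of the near-identical hemoglobin genes, and of Apol9a and Apol9b, are uncertain because such copies can share reads. Ccl2 (chromosome 11, 82035571 to 82037453) fell from 75.5 ± 19.4 to 7.99 ± 0.464 FPKM (limma adjusted p = 2.08e-06), and Has1 (chromosome 17, 17843328 to 17855188) rose with an adjusted p of 3.96e-05.

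In total, limma called 5089 of 11788 genes tested (43.17%), 3304 higher and 1785 lower in YKL-05-099 cells, and 252 of them changed by at least 1 log2 unit (127 higher and 125 lower). Counts of called members in the lists below stand against these shares. After median-of-ratios scaling the calls were split evenly, 2497 higher and 2466 lower, so the excess of higher calls depended on scaling. The values of both groups did not overlap for 39.96% of genes, where chance gives 2.86%. With the mean of the pan-leukocyte markers as a covariate 421 genes were called, and a median standard error 2.08 times that of the fit without it went with this count. The covariate was 1.48 to 2.063 in vehicle and 0.74 to 1.143 in YKL-05-099 libraries. In culture it stood at 0.662, and 4 of its 15 markers reached an FPKM of 1, among them Cytip (5.67) and Ptpn6 (4.23). The covariate may thus hold some expression of the tumor cells themselves. Since it did not overlap between the groups, larger standard errors are built into that fit. A call lost there does not by itself tie a gene to leukocyte RNA.

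**Figure D2:**
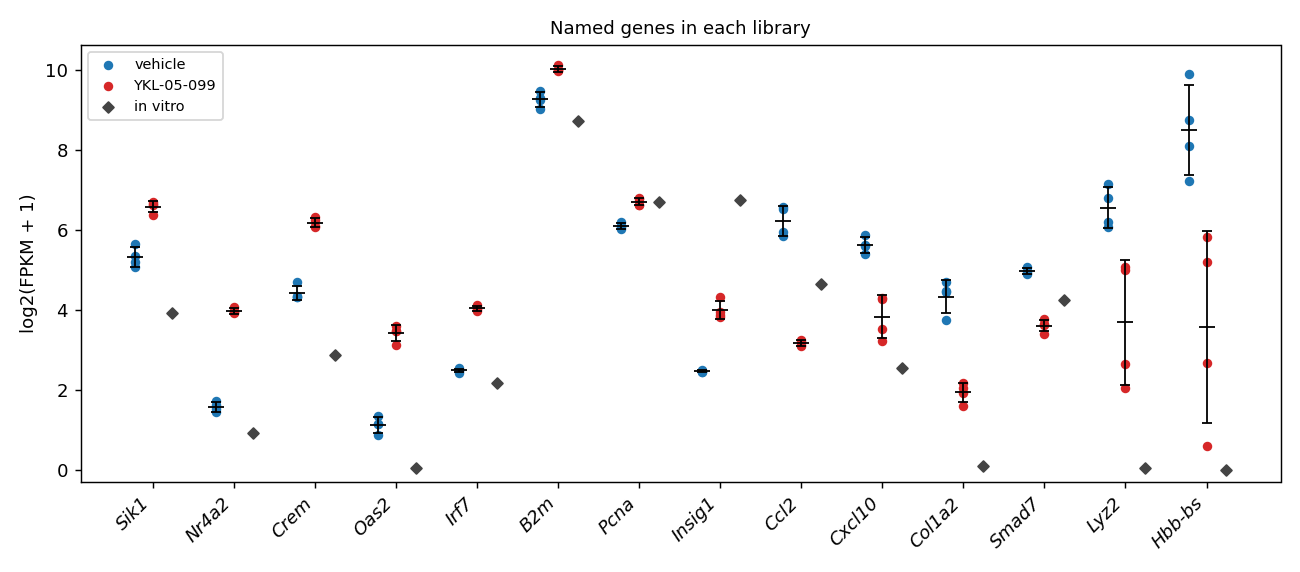
Log2(FPKM + 1) of 14 named genes in every library, with circles for the vehicle and YKL-05-099 libraries, bars for mean ± SD (n = 4) and a diamond for the cultured library. Ccl2 lay at 7.99 ± 0.464 FPKM in YKL-05-099 cells, below every vehicle library, whereas Lyz2 and Hbb-bs differed widely between the YKL-05-099 libraries.

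Among the kinases targeted by the compound, Sik1 transcripts were clearly higher after treatment and Sik2 was not called, and 12 of 20 tested CREB-responsive genes rose. Sik1, itself a CREB target (chromosome 17, 31844248 to 31855792), rose from 39.2 ± 7.07 to 95.05 ± 8.91 FPKM (log2 fold change 1.27, SE 0.115, limma adjusted p = 4.66e-05). Sik3 rose from 22.7 ± 2.05 to 28.2 ± 0.391 FPKM (log2 fold change 0.31, and 0.11 with the mean of the pan-leukocyte markers as a covariate, which ended the call), and Sik2 was 11.4 ± 1.12 FPKM in vehicle and 12.01 ± 1.14 FPKM in YKL-05-099 cells (adjusted p = 0.545). Of 20 tested CREB and CRTC target genes 12 rose and none fell (camera adjusted p = 0.000425, and adjusted p = 0.333 with an estimated correlation). They included Nr4a2, Crem (20.6 ± 2.87 to 71.6 ± 5.82 FPKM), which encodes CREB-family activators and repressors, and the cAMP phosphodiesterase genes Pde4b (21.1 ± 1.45 to 46.1 ± 1.51 FPKM) and Pde4d (6.24 ± 1.09 to 26.1 ± 0.634 FPKM). All 5 tested members of the gluconeogenesis and CRTC2 list rose, Sik1, Nr4a1, Pck2 and Ppargc1a among them (camera adjusted p = 0.00749, and 0.176 as adjusted p with an estimated correlation). Adjusted over the list alone, the counts were also 12 and 5. Macrophage and leukocyte markers were lower in the same libraries, and with the pan-leukocyte covariate 6 of the 20 CREB targets (median 0.77, before 0.73) and 1 of the 5 gluconeogenesis genes (median 0.72, before 0.60) passed the threshold, with larger standard errors.

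Interferon-stimulated and MHC class I antigen presentation genes rose. In the type I interferon list 31 of 35 tested genes rose and Samhd1, named after its value was seen, fell (camera adjusted p = 3.97e-13, and adjusted p = 0.138 with an estimated correlation). Irf7, a transcription factor that amplifies interferon production, went from 4.58 ± 0.186 to 15.4 ± 0.782 FPKM, Irf9 from 9.29 ± 0.402 to 19.99 ± 0.874 FPKM and Rtp4 from 5.84 ± 0.316 to 17.1 ± 1.37 FPKM. In the interferon gamma list 22 of 27 tested genes rose, among them Irgm1, Irgm2 and Gbp3, while Cxcl10 fell (camera adjusted p = 1.39e-05, and adjusted p = 0.468 with an estimated correlation). In the class I list 18 of 20 tested genes rose and none fell (camera adjusted p = 8.02e-05, and adjusted p = 0.468 with an estimated correlation). B2m, the light chain of class I molecules, rose from 619.2 ± 79.3 to 1043 ± 51.1 FPKM, the peptide transporter gene Tap1 from 10.9 ± 0.635 to 18.4 ± 1.49 FPKM, and H2-D1 from 102.9 ± 17.8 to 152.5 ± 8.38 FPKM. The class I genes belong to a family of similar copies, and class I protein was part of the sort gate. Adjusted over the list alone, 31, 24 and 19 genes rose in these lists. The interferon gamma and class I lists share Tap1. Macrophage and leukocyte markers were lower in the same libraries. With the pan-leukocyte covariate 16 of 35 type I interferon genes (median 0.75, before 0.82), 4 of 27 interferon gamma genes (0.46, before 0.55) and 1 of 20 class I genes (0.29, before 0.40) passed the threshold. B2m (log2 fold change 0.74, before 0.76) and H2-D1 (0.62, before 0.58) no longer passed, with folds about as large, and the median standard error of the class I list went from 0.0942 to 0.202.

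Cell cycle genes were higher in YKL-05-099 cells. All 35 tested genes of mitosis and G2/M rose, with log2 fold changes from 0.63 to 1.14 (camera adjusted p = 2.35e-16, and adjusted p = 0.337 with an estimated correlation). The kinesin gene Kif2c rose from 4.37 ± 0.354 to 9.19 ± 0.566 FPKM, and the kinetochore genes Nuf2 and Cenpe rose from 4.30 ± 0.378 to 9.24 ± 0.843 FPKM and from 2.94 ± 0.117 to 6.07 ± 0.538 FPKM. Of 31 tested genes of DNA replication and S phase 30 rose and Rrm1, named after its value was seen, fell (camera adjusted p = 7.88e-10, and adjusted p = 0.337 with an estimated correlation). Pcna, the sliding clamp of DNA polymerases, rose from 67.5 ± 3.75 to 103.6 ± 6.88 FPKM, and Pold1 from 13.8 ± 0.732 to 23.3 ± 1.46 FPKM. Adjusted over the list alone, all 35 mitosis genes and 30 S phase genes rose. Macrophage markers were lower in the same libraries, and with the pan-leukocyte covariate 4 of the 35 mitosis genes (median 0.51, before 0.84) and 3 of the 31 S phase genes (0.35, before 0.56) passed the threshold.

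Cholesterol synthesis genes rose in 19 of 23 cases and none fell (camera adjusted p = 8.06e-07, and adjusted p = 0.247 with an estimated correlation; 20 adjusted over the list alone). Insig1, a sterol-regulated brake on this pathway, went from 4.50 ± 0.0847 to 15.01 ± 2.70 FPKM, the mevalonate kinase gene Mvk from 5.35 ± 0.766 to 13.0 ± 0.607 FPKM and Fdps from 9.56 ± 0.211 to 16.2 ± 1.01 FPKM. Of the 21 unfolded protein response genes 11 rose, with the same count adjusted over the list alone, and none fell (camera adjusted p = 0.0155, and adjusted p = 0.577 with an estimated correlation). The chaperone gene Hsp90b1 rose from 218.4 ± 41.1 to 302 ± 30.8 FPKM and Xbp1 from 168.3 ± 15.2 to 214.3 ± 20.3 FPKM. With the pan-leukocyte covariate 4 of the 23 cholesterol genes passed the threshold (median 0.46, before 0.58). The call of the unfolded protein response list ended when YKL-05-099 replicate 4 was left out (median log2 fold change 0.31), and with the pan-leukocyte covariate its median was -0.02.

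**Figure D3:**
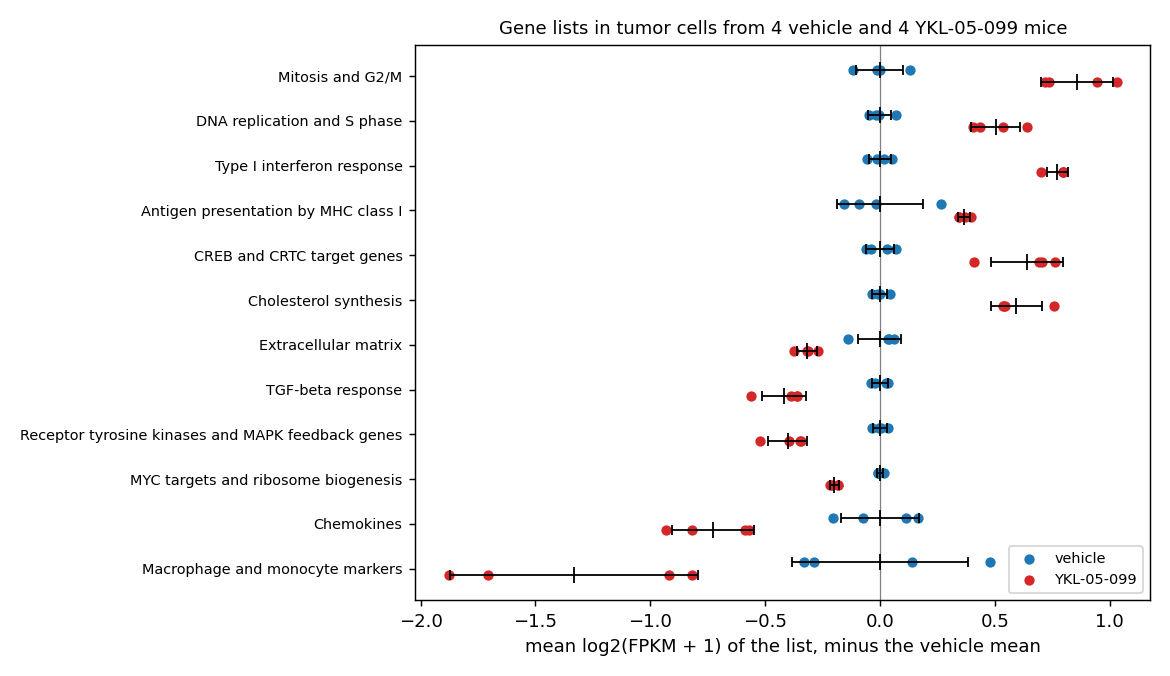
Mean log2(FPKM + 1) of 12 gene lists in each mouse library, relative to the vehicle mean of the list, with bars for mean ± SD of 4 libraries. Mitosis, S phase, interferon, class I, CREB and cholesterol lists lay higher in all 4 YKL-05-099 libraries than in any vehicle library, and the other 6 lists lay lower.

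Chemokine transcripts fell, 11 of 12 tested genes in all (camera adjusted p = 2.13e-06, and adjusted p = 0.212 with an estimated correlation; 11 lower and 1 higher adjusted over the list alone). Next to Ccl2, the related Ccl7 fell from 7.79 ± 1.81 to 0.751 ± 0.363 FPKM, the interferon-inducible Cxcl10 from 48.6 ± 6.86 to 13.9 ± 5.29 FPKM and Cxcl16 from 45.7 ± 2.90 to 34.7 ± 2.68 FPKM. The list of NF-kappaB and inflammatory cytokine genes, which shares Ccl2 and Ccl7, held 10 genes that fell and 4 that rose among 22 (camera adjusted p = 0.00183, and adjusted p = 0.464 with an estimated correlation; 11 and 4 adjusted over the list alone). Its cytokine genes Lif (10.4 ± 0.914 to 4.31 ± 0.427 FPKM) and Csf1 (32.3 ± 3.04 to 22.1 ± 0.255 FPKM) fell. Leukocyte transcripts were lower in the same libraries. With the pan-leukocyte covariate 4 of the 22 genes of this list passed the threshold (median -0.13, before -0.38), and 3 of the 11 chemokines did (median of the 11 -0.343, before -1.80). These were Ccl2 at a log2 fold change of -2.46 (SE 0.24, limma adjusted p = 0.00235), Ccl7 at -1.54 (SE 0.242) and Cx3cl1, named after its value was seen, at -0.62 (SE 0.141, limma adjusted p = 0.0498). Cxcl10 (-1.87, before -1.80) and Cxcl16 (-0.34, before -0.39) no longer passed, with folds about as large.

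The lists of signaling-feedback genes, growth factors, TGF-beta responses and YAP targets were called lower, with members that moved both ways. Of 27 receptor tyrosine kinase and MAPK feedback genes 17 fell and 4 rose (camera adjusted p = 5.7e-06, and adjusted p = 0.145 with an estimated correlation). The Ras pathway inhibitor gene Spred2 fell from 19.4 ± 1.06 to 8.63 ± 0.575 FPKM, Spred1 from 18.9 ± 1.53 to 10.6 ± 0.893 FPKM and the receptor gene Pdgfra from 12.1 ± 1.37 to 5.95 ± 0.354 FPKM, whereas the EGFR ligand gene Ereg rose from 0.390 ± 0.0563 to 2.79 ± 0.434 FPKM. Among 20 growth factor genes 9 fell and 3 rose (camera adjusted p = 0.00282, and adjusted p = 0.145 with an estimated correlation), with falls of Pdgfb (19.6 ± 2.06 to 5.96 ± 0.762 FPKM) and Fgf18 (10.4 ± 1.24 to 3.50 ± 0.293 FPKM) and a rise of Vegfb. In the TGF-beta response list 6 of 14 fell and 2 rose (camera adjusted p = 0.0155, and adjusted p = 0.212 with an estimated correlation). Its member Smad7, an inhibitor of the pathway, fell from 30.3 ± 1.78 to 11.2 ± 1.24 FPKM, and Skil fell as well, while Inhba rose. Among 22 YAP and TEAD targets 9 fell, such as Ajuba and Ptpn14, and 2 rose (camera adjusted p = 0.000533, and adjusted p = 0.261 with an estimated correlation). Adjusted over the list alone, 20, 9, 6 and 11 genes fell in these lists and 4, 4, 2 and 2 rose. In the fit with the pan-leukocyte covariate 8, 3, 2 and 3 members passed the threshold, with medians of -0.38 (before -0.48), -0.20 (before -0.25), -0.33 (before -0.14) and -0.21 (before -0.26) and median standard errors of 0.214 (before 0.107), 0.228 (before 0.112), 0.184 (before 0.0885) and 0.17 (before 0.0942).

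Of 27 extracellular matrix genes 13 fell and 3 rose, with equal counts adjusted over the list alone (camera adjusted p = 4.91e-05, and adjusted p = 0.261 with an estimated correlation). The proteoglycan gene Bgn fell from 202.4 ± 17.2 to 96.2 ± 6.78 FPKM, Timp3 from 251.1 ± 6.46 to 156.1 ± 14.5 FPKM and Col1a2 from 19.7 ± 5.27 to 2.86 ± 0.627 FPKM. Of 7 tested fibroblast markers 5 fell, Col1a2, Col1a1, Pdgfra and Loxl1 among them (camera adjusted p = 0.000415, and adjusted p = 0.174 with an estimated correlation; 5 adjusted over the list alone). In culture 6 members of that marker list reached an FPKM of 1, but Col1a2 stood at 0.0668 FPKM there. Of 23 immunosuppressive ligand and enzyme genes 9 fell, including the B7-family genes Vtcn1 (2.48 ± 0.523 to 0.719 ± 0.212 FPKM) and Cd276, and 3 rose, including Lgals9, as also adjusted over the list alone (camera adjusted p = 0.00553, and adjusted p = 0.176 with an estimated correlation). The call of this list ended with the pan-leukocyte covariate (median -0.08, before -0.25), and Vtcn1 (log2 fold change -0.61, before -1.01) and Cd276 (-0.57, before -0.53) no longer passed. In that fit 3 matrix genes and 2 fibroblast markers passed, with medians of -0.19 (before -0.19) and -0.49 (before -0.44) and median standard errors of 0.166 (before 0.0864) and 0.163 (before 0.0788).

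Ribosome biogenesis genes fell by small amounts, and most ribosomal protein genes were not called. Of 30 MYC target and ribosome biogenesis genes 17 fell and none rose (camera adjusted p = 6.18e-07, and adjusted p = 0.145 with an estimated correlation; 18 adjusted over the list alone), with Rrp12 going from 7.44 ± 1.04 to 3.83 ± 0.406 FPKM and Eif4a1 from 401.8 ± 8.77 to 313.1 ± 10.4 FPKM. Of 45 ribosomal protein genes 9 fell, Rpl12, Rpl5, Rps13 and Rps6 among them, 36 were not called, and the list median was -0.11 (camera adjusted p = 2.13e-06, and adjusted p = 0.468 with an estimated correlation). Adjusted over the list alone 5 fell, and over all genes tested 1785 of 11788 fell. Of the 30 and 45 genes, 2 and 0 passed the threshold with the pan-leukocyte covariate, with medians of -0.18 (before -0.20) and -0.07 (before -0.11) and median standard errors of 0.125 (before 0.0601) and 0.113 (before 0.0556).

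A further 5 lists were called by a narrow margin and held members that moved both ways or few that passed. Of 22 glycolysis genes 10 fell, Eno1, Pgam1 and Pfkl among them, and 4 rose, Hk1 among them (camera adjusted p = 0.0176, and adjusted p = 0.554 with an estimated correlation). Of 23 hypoxia genes 9 fell, such as Egln1 and P4ha1, and 4 rose, such as Egln3 (camera adjusted p = 0.0155, and adjusted p = 0.575 with an estimated correlation). Of 20 immediate early genes 5 fell, Btg2 and Egr2 among them, and 3 rose, Nr4a1 and Klf4 among them (camera adjusted p = 0.0361, and adjusted p = 0.639 with an estimated correlation). Of 16 ovarian and Mullerian epithelial markers 6 fell, including the transcription factor genes Emx2 and Gata6, and 2 rose, including Krt18 (camera adjusted p = 0.048, and adjusted p = 0.468 with an estimated correlation). Of 8 genes of the MHC class II antigen presentation list 1, Ctss, fell (camera adjusted p = 0.0327, and adjusted p = 0.566 with an estimated correlation). Ctss is also on the macrophage marker list, and its log2 fold change was 0.52 with the pan-leukocyte covariate. H2-Aa, H2-Eb1 and Cd74 were not called, and Cd74 was 327.4 ± 140.5 FPKM in vehicle and 216.1 ± 33.6 FPKM in YKL-05-099 cells. H2-Aa did pass with median-of-ratios scaling (log2 fold change -0.66). Without vehicle replicate 3, H2-Aa (-0.76) and Cd74 (-0.70) passed. Adjusted over the list alone, 11, 9, 5, 7 and 1 genes fell in these lists. The medians of the glycolysis, hypoxia, immediate early, Mullerian and class II lists were -0.18, -0.19, -0.35, -0.13 and -0.39. Median-of-ratios scaling ended the calls of the last 4, at medians of -0.25, -0.41, -0.19 and -0.45. That scaling also moved the median of all genes tested from 0.0541 to -3.77e-05. The lower list medians therefore do not set these lists further apart from other genes. Quantile normalization ended all 5 (-0.27, -0.29, -0.29, -0.12 and -0.40) and the TGF-beta call (-0.16, before -0.14). The pan-leukocyte covariate ended all 5 too (-0.05, -0.10, 0.04, -0.01 and -0.35), and the replicate block ended the Mullerian call. Leaving out a single library ended the immediate early call (vehicle replicate 4, median -0.28; YKL-05-099 replicate 4, median -0.13), the class II call (vehicle replicate 4, median -0.10; YKL-05-099 replicate 4, median -0.27) and the hypoxia call (vehicle replicate 1, median -0.14). The Mullerian call ended without vehicle replicate 1, 2 or 3 or without YKL-05-099 replicate 2 or 4, at medians from -0.14 to -0.11.

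Transcripts typical of blood and immune cells were present in the vehicle libraries and lower after treatment. Of 11 tested macrophage and monocyte markers 10 fell, as also adjusted over the list alone (camera adjusted p = 5.18e-06, and adjusted p = 0.425 with an estimated correlation). Lyz2, the macrophage lysozyme gene, was 109.7, 141.7, 66.5 and 72.2 FPKM in vehicle replicates 1 to 4 and 5.27, 30.9, 32.4 and 3.11 FPKM in YKL-05-099 replicates 1 to 4, Apoe fell from 170 ± 66.4 to 16.9 ± 8.56 FPKM and Csf1r from 3.13 ± 1.23 to 0.495 ± 0.201 FPKM. Of 8 tested pan-leukocyte markers 6 fell (camera adjusted p = 5.74e-05, and adjusted p = 0.337 with an estimated correlation; 8 adjusted over the list alone), Laptm5 and Fermt3 among them. Of 7 erythroid and platelet markers 6 fell, as also adjusted over the list alone (camera adjusted p = 0.00871, and adjusted p = 0.468 with an estimated correlation). Hbb-bs was 451.3 ± 354.6 FPKM in vehicle cells and 24.2 ± 26.0 FPKM in YKL-05-099 cells, while the integrin gene Itga2b rose from 8.15 ± 1.79 to 28.9 ± 0.551 FPKM. Igkc fell from 19.7 ± 14.3 to 0.217 ± 0.179 FPKM. In culture 2 of 20 macrophage markers reached an FPKM of 1, and Lyz2 stood at 0.0237 FPKM.

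Of 50 lists tested, 9 were called higher and 19 lower with the preset correlation and 0 with an estimated one, where 10 lists had an unadjusted p under 0.05, and fry called 30. Of the 28 lists called, 7 were not called by fry: unfolded protein response (adjusted p = 0.0584), erythroid (0.111), Mullerian (0.111), glycolysis (0.154), class II (0.204), hypoxia (0.308) and immediate early (0.46). No cage, day or batch is given by the labels, and a prefix of the library names coincides with treatment, so batch and treatment cannot be separated.

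The second comparison set cells grown in culture against tumor cells from vehicle-treated mice. It rests on 1 cultured library, so differences have no replicate check and no p-value. The mouse cells also came from ascites and through a sort, and their libraries held transcripts of blood and immune cells. Growth site, handling and such transcripts cannot be told apart in this comparison, also for the immediate early genes. Of 12296 genes compared, 256 were apart and higher in culture and 376 apart and lower. Spp1, encoding osteopontin, was 650.8 FPKM in culture and 5.08 ± 0.695 FPKM in vehicle cells. Sqle, Ankrd1, Aldh1l2, Emb, Ccnd2, Mir686, Ero1l and Steap1 were also among the 10 with the largest difference, at differences of 4.34 to 5.13 log2 units. Mir686 is a short microRNA gene (chromosome 14, 54616677 to 54616785), for which FPKM is uncertain. In the other direction the immediate early gene Fos was 5.60 FPKM in culture and 1756 ± 274.7 FPKM in vehicle cells, and Igfbp2, Cst12 and Fxyd1 were 2.19, 1.55 and 2.49 FPKM in culture against 263.1 ± 45.1, 199.6 ± 25.1 and 270.5 ± 8.86 FPKM. Hbb-bs, Hba-a1 and the class II gene H2-Aa were listed at 0 in culture, and Cd74, H2-Eb1 and Lyz2 were at 0.184, 0.0483 and 0.0237 FPKM.

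By list, cholesterol synthesis genes stood highest in culture, with a median difference of 2.57 log2 units and 17 of 23 genes apart. Insig1 was 105.6 FPKM in culture and 4.50 ± 0.0847 FPKM in vehicle cells. Mitosis genes followed (median 2.25, 28 of 35 apart), with Aurka at 49.1 FPKM against 5.66 ± 1.24 FPKM and Plk1 at 55.1 FPKM against 6.85 ± 0.855 FPKM. Genes of the ATF4 and amino acid response (median 1.76, 10 of 25 apart), hypoxia (1.68, 10 of 24) and glycolysis (1.58, 4 of 22) were higher too, for example Chac1, P4ha2 and Aldoc. Each of these 5 medians lay above all 10000 random lists. The random draws ignore that genes of a pathway vary together, so such placements, here and below, are not p-values. Lower in culture were MHC class II genes (median -4.89, 7 of 8 apart), immediate early genes (-2.98, 14 of 20 apart), MEF2 targets (-1.79, 6 of 12 apart) and interferon gamma genes (-1.52, 10 of 28 apart and lower, and Upp1, named after its value was seen, apart and higher). Their medians lay below all 10000 random lists. Egr1 was 29.8 FPKM in culture and 1399 ± 197.2 FPKM in vehicle cells, Klf4 13.6 against 109.8 ± 16.6 FPKM and Gbp2 0.980 against 22.8 ± 7.95 FPKM. CREB and CRTC targets also stood lower (median -0.98, 7 of 22 apart and lower, and Areg and Bdnf, named after their values were seen, apart and higher), as did mesothelial markers (-1.51, 6 of 14 apart), although the mesothelial and Mullerian marker Upk3b was still 118.3 FPKM in culture against 561.7 ± 11.3 FPKM. Macrophage, erythroid and pan-leukocyte markers had medians of -3.82, -4.74 and -1.84. The number of genes apart depended on the rule, with 2480 at a difference of at least 1 and 1238 with a pseudocount of 0.1.

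**Figure D4:**
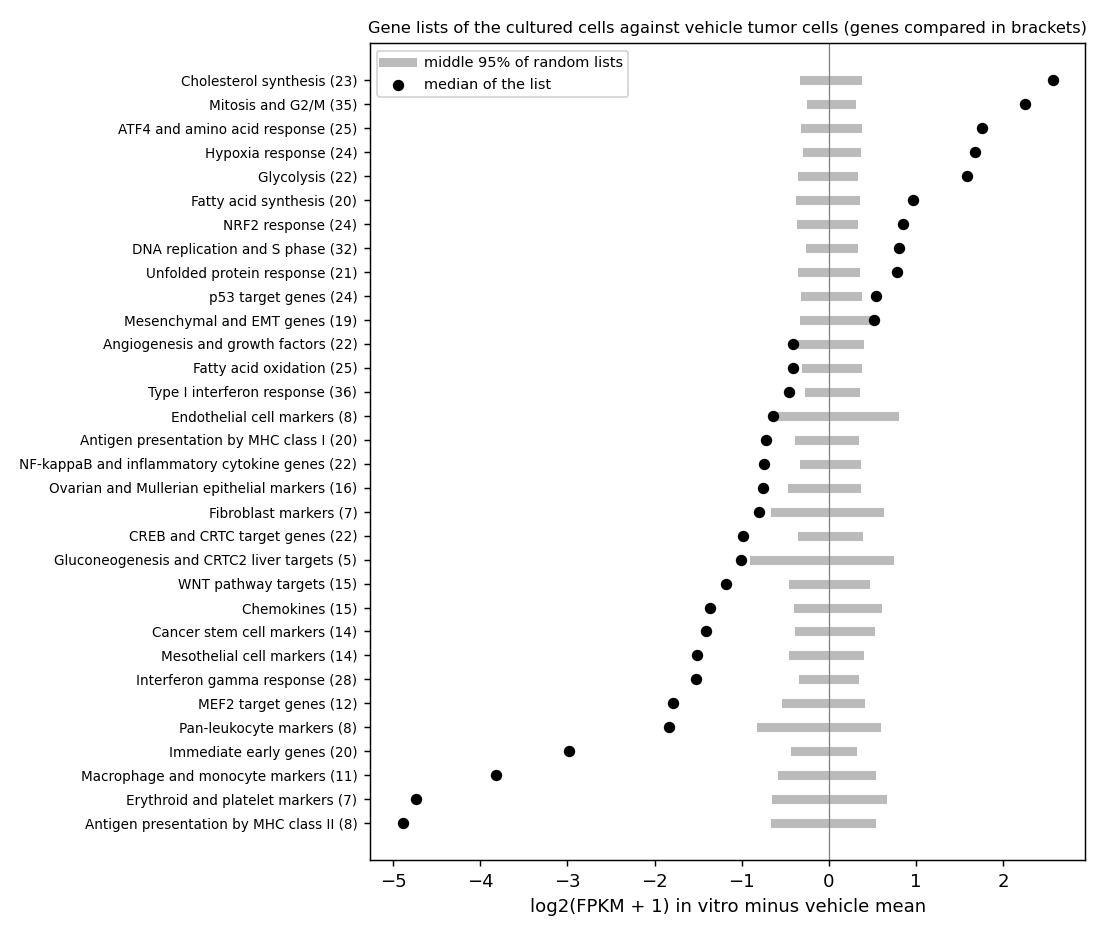
Median difference in log2(FPKM + 1) between the cultured library and the vehicle mean for 32 gene lists outside the middle 95% of 10000 random lists, shown as grey bars. Cholesterol synthesis stood highest at 2.57 and MHC class II lowest at -4.89.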

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

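The tests in this part were all planned, and none was chosen only after its result was seen. In each group of 4 libraries the gap between the highest or lowest value and its nearest neighbour was divided by the whole range on the log2(FPKM + 1) scale. A share above Dixon's 95% critical value for 4 libraries marks a library far from the other 3. Of 380 groups of values tested 24 passed, where chance gives about 19, so the number was near that of chance, although 11 of the 24 fell on vehicle replicate 4, and the values are given without an explanation.

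Vehicle replicate 4 held the value far from the other vehicle libraries for Il33 (share 0.888; 12.3 FPKM against 5.1 to 5.65), Crem (0.934; 24.9 against 19 to 19.4), Btg2 (0.871; 484 against 450 to 454), Hsp90b1 (0.946; 280 against 196 to 200), Ereg (0.858; 0.474 against 0.352 to 0.369), Itga2b (0.844; 10.8 against 7.01 to 7.51), Sqle (0.894; 4.41 against 2.29 to 2.47), Lox (0.897; 12.2 against 27.1 to 29.6) and Rspo1 (0.939; 131 against 99.3 to 101). The mean log2(FPKM + 1) of the immediate early list (0.8291; 7.52 against 7.19 to 7.25) and of the extracellular matrix list (0.877; 4.14 against 4.32 to 4.34) stood apart in that library too. Vehicle replicate 2 stood apart for Loxl1 (0.879; 54.9 against 47.3 to 48.1 FPKM) and Emb (0.961; 6.9 against 5.42 to 5.47), and vehicle replicate 1 for Aldh1l2 (0.864; 0.557 against 0.438 to 0.453).

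Among the YKL-05-099 libraries, replicate 4 stood apart for Nr4a1 (0.851; 146 against 252 to 278 FPKM), Btg2 (0.923; 162 against 317 to 335), Dhcr7 (0.852; 45.9 against 48.3 to 48.8) and the mean of the TGF-beta list (0.871; 3.5 against 3.68 to 3.71). Replicate 1 stood apart for Irf9 (0.924; 18.7 against 20.4 to 20.5 FPKM), Lgals9 (0.93; 82.6 against 88.2 to 88.6) and the means of the type I interferon list (0.973; 3.39 against 3.48 to 3.49) and the cholesterol list (0.956; 3.8 against 3.58 to 3.59). Replicate 3 stood apart for Fdps (0.831; 14.7 against 16.5 to 16.9 FPKM) and the mean of the ribosomal protein list (0.891; 9.11 against 9.01 to 9.02).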

How the results depend on the processing

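The tests on genes at an FPKM of at least 1 in culture (4777 genes called) and on protein-coding genes (5011 called) were chosen only after the results were seen. Against 5089 genes called by limma, 421 passed with the pan-leukocyte covariate (2390 at an unadjusted p under 0.05) and 252 at a minimum change of 1 log2 unit. The minimum change asks for more by construction. With the covariate the median standard error was 2.08 times as large. A larger standard error follows from a covariate whose values did not overlap between the groups. Some folds shrank (median of the mitosis list 0.844 to 0.505) and others did not (CREB 0.734 to 0.773). How much of the lower count goes back to leukocyte RNA cannot be told from this fit. Other settings called from 4106 (mean FPKM of at least 5) to 6123 genes (adjusted p under 0.1), and leaving out single libraries gave 4226 to 5533. Of 28 lists called, 0 were called with an estimated correlation (10 at an unadjusted p under 0.05; fry called 30, 21 of them among the 28), and leaving out single libraries gave 24 to 30. Without a filter the immediate early and Mullerian calls ended, and with a mean FPKM of at least 5 the hypoxia call ended. Among named genes, Btg2, Egr2 and the unfolded protein response gene Syvn1 no longer passed without a filter, and Rps13 no longer passed with quantile normalization (-0.10). The labels number both groups alike, but the numbers did not pair the libraries (across genes, r of each pair was -0.0184, 0.133, -0.0467 and 0.172); with the replicate block 4830 genes and 28 lists were called, 27 of them among the 28, since the Mullerian call ended. With the covariate 58 of 123 named genes were on the same side of the threshold, 59 no longer passed and 6 reversed: Hbb-bs (0.1868), Hba-a1 (0.1646), Lyz2 (0.1374), Ctss (0.5193), Cd53 (0.1225) and Sik2 (-0.2509), as did camera's direction for the unfolded protein response (median -0.0153) and erythroid lists (0.165). The covariate fit called 19 lists, 18 of them among the 28. The calls of the immediate early (median 0.037), macrophage (0.222), pan-leukocyte (0.0169), immunosuppressive (-0.0817), Mullerian (-0.013), hypoxia (-0.101), glycolysis (-0.0546) and class II (-0.35) lists ended. The pan-leukocyte call was bound to end, since the covariate is the mean of that list. Sik2, not called, also reversed with quantile normalization (-0.01364). Cd53 is a member of the list behind the covariate, and the cause of the other reversals was not tested. A reversal here is a change of sign only. With the covariate the median standard error was 0.472 in the macrophage list and 0.448 in the erythroid list. The values of Hbb-bs, Hba-a1 and Lyz2 lay below these and are not read as rises. Beside 632 genes apart in culture, a limma fit of all 9 libraries, in which the lone library is assumed to vary like the others, called 7952; a difference of at least 1 gave 2480, a pseudocount of 0.1 gave 1238, and leaving out single vehicle libraries gave 633 to 649. The depth cannot be turned into an interval for single genes, since counts were not recovered.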

Other observations

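The tests of the order of libraries, of chemokines parted by their level in culture, of Mullerian markers and of the mitosis list with the covariate were chosen only after the results were seen; the order tests took the place of correlations computed first, of which that of immunoglobulin with macrophage means had been read as evidence against a shared carry-over and is now left open. The bound that at least 50% of members pass was also added after the values were seen, and it turned the reading of mitosis with the covariate from evidence against leukocyte RNA to open. The tests of all chemokines with the covariate, of mitosis after scaling and of other splits were planned.

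Several lists not called held members that changed, where 43.17% of all genes tested were called, so such counts alone do not set a list apart. Of 21 heat shock genes 11 rose and 1 fell (camera adjusted p = 0.113), and of 22 genes of the ATF4 and amino acid response 9 rose and 3 fell (camera adjusted p = 0.327). Of 12 MEF2 targets 2 rose and 5 fell (camera adjusted p = 0.0843). In culture WNT targets stood lower than in vehicle cells (median -1.18), with Rnf43 at 0.0300 FPKM against 29.8 ± 2.58 FPKM and Axin2 at 1.11 against 22.5 ± 3.16 FPKM. Chosen after its values were seen, Fbxw7 was 5016.69, 4246.94, 6702.28 and 3950.52 FPKM in vehicle replicate 4 and YKL-05-099 replicates 1, 3 and 4, and 5.54 to 7.01 FPKM in the other 5 libraries. Ighj1, Ighj2 and Ighj4, chosen likewise, were 6035.16, 16052.9 and 6352.15 FPKM in vehicle replicate 3 and listed at 0 in the other libraries. Whether these spikes arose in quantification was not tested, and they are not read as expression. The class II gene Cd74 was 170.4 to 532.4 FPKM in the mouse libraries.

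Of the 35 splits of the 8 mouse libraries into 4 against 4, only the real 1 called as many as 5089 genes, and the highest other split called 1 gene. The other splits mix the treatments, so the difference between treatments widens the spread within their groups and low counts were bound to follow. With 35 splits the share of the real 1 cannot go below 1 in 35, so the test does not exclude chance. For lists, too, only the real 1 called as many as 28, but the highest other split called 27, the 16 splits with 3 libraries of a treatment together called 14 to 27, and the 18 splits with 2 and 2, which hold no treatment contrast, called 3 to 17. With the preset correlation many lists were thus called where no treatment contrast was present.

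Macrophage, erythroid and immunoglobulin transcripts all fell in cells sorted as CD45-negative and MHC class I-positive. The gate as labelled names no erythroid marker, so erythroid RNA need not mark CD45-positive cells that the sort missed. Within the groups, the macrophage and erythroid means stood in the same order in 12 of 12 pairs of libraries (exact permutation p = 0.00174 over 576 orders), as RNA of both carried through the sort may give. For the immunoglobulin and macrophage means 8 of 12 pairs did (exact permutation p = 0.241), 2 of 6 in vehicle and 6 of 6 in YKL-05-099, and the ratio of Igkc to Lyz2 was 0.0668 to 0.599 in vehicle and 0.00575 to 0.0316 in YKL-05-099 libraries; the uneven ratio goes against a joint carry-over, but as single top genes and a difference between groups it leaves this open. Lyz2 was 66.5 to 141.7 FPKM in vehicle and 3.11 to 32.4 FPKM in YKL-05-099 libraries, while 2 of 20 macrophage markers reached an FPKM of 1 in culture. Whether treatment or the sort lowered these transcripts cannot be told apart, since the labels do not say how sorting was spread over the groups.

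Chemokine transcripts may have fallen because fewer leukocytes were carried over. With the pan-leukocyte covariate the median log2 fold change of all 11 went from -1.80 to -0.343, which leaves the set as a whole open. For the 5 under an FPKM of 1 in culture (Cxcl2, Ccl3, Ccl4, Ccl6, Ccl9, chosen after their values were seen) it went from -1.87 (quartiles -2 to -1.49) to 0.0575 (0.0344 to 0.506), with 0 passing, as carry-over predicts. A low level in culture does not mark leukocyte origin, so their source stays open. Cd74, at 0.184 FPKM in culture, stood at 2.07 to 7.38 times Lyz2 in vehicle and at 6.86 to 54.9 times Lyz2 in YKL-05-099 libraries. For the 6 at an FPKM of at least 1 in culture (Cxcl1, Cxcl10, Cxcl16, Cx3cl1, Ccl2, Ccl7, chosen likewise) the median went from -1.42 to -1.38, with 3 passing. These were Ccl2, Ccl7 and Cx3cl1, the last at a limma adjusted p of 0.0498, so the bound on calls, added after the values were seen, was only just reached. For Ccl2 and Ccl7 this argues against carried-over leukocytes as the whole cause, and for the others it is left open. A lower expression of Ccl2 and Ccl7 in the tumor cells after treatment is a hypothesis, found and tested on the same data.

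Mitosis and S phase genes rose, and a lower share of other cells in the libraries could raise them. Mullerian markers, which such a shift would raise too, had a median of -0.128 (quartiles -0.502 to 0.117). That list was itself called lower after treatment, so it is not a neutral gauge of dilution. The median over all genes tested, taken up after the results were seen, was 0.0541 against 0.844 for mitosis. This argues against less dilution as the whole cause. The mitosis median was 0.796 after median-of-ratios scaling, which argues against scaling. With the pan-leukocyte covariate the mitosis median went from 0.844 (quartiles 0.759 to 0.963) to 0.505 (0.433 to 0.599) and 4 of 35 genes passed. Camera at the preset correlation still called the list, but most gene calls ended, with a smaller fold and a median standard error that went from 0.0955 to 0.151. By the median alone this would argue against leukocyte RNA as the whole cause; by the bound on calls, added after the values were seen, the parts of treatment and leukocyte RNA cannot be told apart.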
